A study of Metallosphaera sedula DSM 5348 and Metallosphaera sedula with 9 samples.

How the data were processed

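RNA of 2 thermoacidophilic archaea, Metallosphaera prunae (strain DSMZ10039) and Metallosphaera sedula (strain DSMZ5348), was compared on spotted 2-colour arrays made for M. sedula. The series holds 9 samples, each a comparison of 2 RNA pools, on 11 slides. Per the labels, RNA from biological repeats was pooled for each condition before cDNA synthesis, so each condition is 1 pool, and the spread between cultures was not measured. There is therefore no test between conditions, and the number of arrays limits the precision. Also per the labels, M. prunae cDNA was hybridised to the M. sedula array because M. prunae genes mapped to the M. sedula genome.

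Per the file headers, each slide's file gives the mean foreground intensity and median local background intensity of each spot at the wavelengths of Cy5 and Cy3. It also gives the percent of saturated pixels and the scanning software's spot flag, also per the file headers. These columns carry no background correction or normalization. Each slide had 15552 spots, of which 3912 were empty. The rest were 5 spots for each of 2328 probes, of which 2258 have a plain number from 1 to 2296 as their ID, 57 have an ID with nc_, 11 carry an M. sedula locus tag with a prefix, and 2 have other IDs. The meaning of nc_ is not given in the sources used here. The deposited table of the authors' processed values holds log ratios, taken here as log2, 1 per probe and sample. Its normalization is not given in the sources used here. Its log base is not stated. The slopes of the fitted ratios on it for the shock comparisons and the U3O8 pair, 0.64 to 0.92, lay just below those on true log2 ratios in a test on simulated data (0.71 to 0.95). For a table in natural logs without compression of its own, slopes of 1.02 to 1.37 would follow. Its sign followed the first RNA of each sample title minus the second, judged from the scanner values, and its columns closed around both loops of slides within 1e-09. The column medians of the authors' deposited table, turned as in the text, lay between -0.08 and 0.09.

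The contents of each dye channel came from the labels, except for the M. prunae 60 min slides, where the labels give both dyes to both channels. Their direction is called likely. It rests on the slides' own names, which matched the labels for every other slide, and on the sign of the authors' deposited table. Background was corrected by normexp with an offset of 50 in limma 3.58.1 under R 4.3.3, and each slide was normalized by loess with empty and flagged spots given no weight. Log2 ratios of the spots of a probe were averaged. The offset pulls ratios of dim spots towards 0. In a test on simulated data with 200 of 2258 numbered probes changed, fitted ratios had a slope of 0.71 on the true ones for the U3O8 pair, and of 0.55 among the probes below the median signal. The test recovered 76% of changes of 2 on the log2 scale for that pair, which missed the limit of 80% first set for all pairs. The limit was then set at 90% for the shock comparisons alone, and all of these met it. For M. sedula at 60 min it recovered 100% of them, with a slope of 0.89.

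The 9 slides of untreated and shocked cells join 7 pools in loops. A least-squares fit of the log2 ratios on the pools, with 1 dye term per probe, gave every comparison among them. It leaves 2 residual degrees of freedom per probe with all slides, with the M. prunae swap slides entered as 2 rows. Errors given as hybridisation SE come from this fit after limma's moderation (prior SD 0.37, prior df 10.5). For the U3O8 pair, a separate dye swap of 2 slides, the error is 0.5 times the absolute difference of the slides, which can come out near 0 by chance. A probe counted as higher or lower when the ratio was at least 2-fold. For the U3O8 pair both slides also had to lie on the same side. Only numbered probes above background entered the counts. Above background meant a mean signal over the 95th percentile of empty spots in at least 1 channel of each slide joining the pair. A second count is limma's moderated test at an adjusted p of 0.05 (Benjamini-Hochberg). It tests hybridisation error between 2 pools and says nothing on the spread between cultures. Simulated unchanged pools were run 100 times through the same loops to give chance overlaps and correlations. They used the same error sizes as the fit. For the untreated pair and 3 h comparisons, simulated counts and covariances are thus likely too small, and the counts of limma's test too large. Figures were drawn with matplotlib 3.10.9.

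The files do not pair probe numbers with genes, and no annotation was used here. The rule for named genes, set before the data were examined, took the 8 highest and 8 lowest ratios per comparison among probes at least 2-fold apart with the same sign on the direct slides. Because the probes carry no gene names, 2 of each are printed by ID. The rest of that rule and the gene lists defined by product text could not be applied. Lists with locus numbers (terminal oxidases and iron oxidation, sulfur oxidation and reduction, carbon fixation, copper resistance) appear only among the closing observations, on the unproven assumption that probe numbers are locus numbers. Their ranges were recalled, not read against product texts. Where only some channels of a pool were above background for a printed probe, their number is given with its ratio or its difference. Where a pool was saturated, or not above background, on all its slides, the size of the ratio is not exact. For probes printed as highest or lowest between 2 pools, a value from channel means after loess and Aquantile normalization then stands beside the fit. A pool not above background was set no lower than the dimmest value above background. The means take in each pool in both dyes equally often, but partly on different slides, so the value is no strict bound.

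Alternatives set before the data were examined were no background correction, median centring, the median of spots, all flagged spots kept, no filter on dim probes, no dye term, the direct slide alone, the authors' deposited table, and each slide left out. The counts, shared probes, printed ratios and list medians were recomputed under these. Added after seeing the data were the recomputed shared probes, the M. prunae 60 min direction turned (for the counts and shared probes, with list values beside them), a dye term for each of the 2 slide layouts, and the M. prunae swap averaged before the fit. Layouts differ in spot diameter: 90 to 100 on the M. prunae 60 min slides and on the M. sedula slides of 15 and 60 min, and 200 on all others. Each loop lies in 1 layout, so the fit with a dye term per layout is also the fit within layouts.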

Results

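Transcripts of Metallosphaera prunae and M. sedula were compared in cells grown at 70 °C in medium of pH 2 that held yeast extract (0.2 wt%), untreated or shocked with 1 mM uranyl acetate, a soluble uranium salt. M. sedula was sampled 15 min, 60 min and 3 h after the shock, and M. prunae 60 min and 3 h after it. A further pair compared both species after 2 days on 0.1 wt% U3O8, a solid uranium oxide, without yeast extract and with added CO2. Each condition was 1 RNA pool, so no value below has a replicate culture behind it, and errors are hybridisation SE. Median signal over background ran from 116 (Cy5, first U3O8 slide) to 2565 (Cy3, M. sedula 15 min slide). At least 80.2% of numbered probes lay above the empty spots in each channel, except in the untreated M. sedula channel of the slide comparing untreated cells, where 42.9% did. Probes are given by their number on the array because the files do not pair numbers with genes.

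In M. sedula the number of probes at least 2-fold apart from untreated cells was larger at each later time of uranyl acetate. The 15 and 60 min slides had a spot diameter of 100, and the 3 h slides of 200. Between 60 min and 3 h, time therefore cannot be told apart from slide layout. At 15 min 57 probes were higher and 54 lower, of 2237 compared. At 60 min 197 were higher and 177 lower, of 2245, and at 3 h 255 were higher and 270 lower, of 2180. Probes at least 4-fold apart numbered 1 higher and 4 lower at 15 min, 28 and 24 at 60 min, and 52 and 59 at 3 h. limma's moderated test of hybridisation error called 65, 413 and 555 probes at an adjusted p of 0.05. Unchanged pools simulated through the same slides gave a mean of 4.6, 5.5 and 7.3 probes at least 2-fold apart. The test and the simulation used 1 error size per probe for all slides. Mean ratios around the loop with the 3 h slides spread more (SD 0.35) than around that of the 15 and 60 min slides (SD 0.14). The 3 h test count is therefore likely too large, and the 3 h simulated count and SE too small. Without the M. sedula 60 min slide the 60 min count was 551, above the 525 of the full fit at 3 h. On the direct slides alone the counts at 60 min and 3 h were 402 and 551, on slides of different layouts. With each direct slide left out they were 551 and 950. The 3 h estimate then sums the error of more slides, in the loop of larger error, so these last counts cannot speak for the order. Without its direct slide the 15 min count was 435 and the 3 h count 950, against 111 and 525 with it, and the authors' deposited table gave 75 higher and 95 lower at 15 min, and 332 higher and 321 lower at 3 h.

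**Figure D1:**
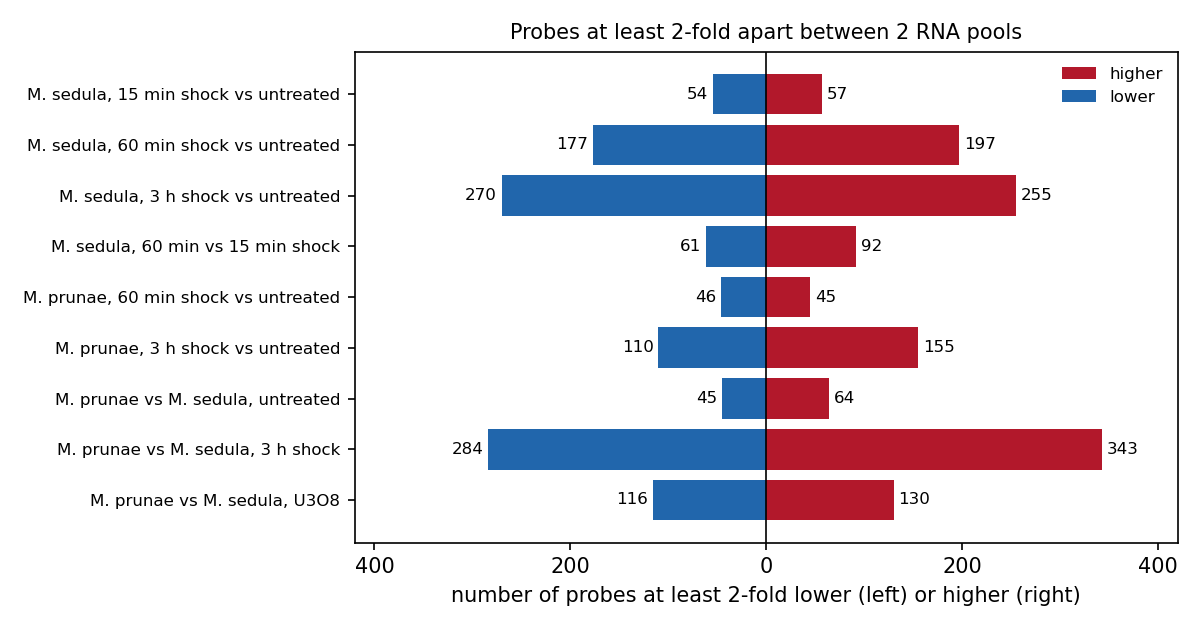
Number of numbered probes at least 2-fold lower (bars to the left) or higher (bars to the right) in the first of 2 RNA pools, for the 9 comparisons of the study; each condition is 1 pool, and there are no error bars. M. sedula went from 57 higher and 54 lower at 15 min to 255 higher and 270 lower at 3 h, on slides of a different layout.

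The M. sedula probes with the highest ratio at 15 min were probe 327, at 3.20 ± 0.39 on the log2 scale, and probe 509, at 1.92 ± 0.35. Untreated M. sedula was above background in 3 of 4 channels for probe 327, which was still at 2.64 ± 0.39 at 60 min and at 0.90 ± 0.42 at 3 h. The lowest at 15 min were probe 1248, at -2.20 ± 0.29, and probe 323, at -2.08 ± 0.28. Both stayed low, at -3.40 and -2.60 at 60 min and at -1.59 and -2.23 at 3 h. At 60 min the highest were probe 490, at 3.81 ± 0.28 (14.1-fold), and probe 491, at 3.49 ± 0.30 (11.3-fold). At 3 h probe 490 was at 1.26 ± 0.30, with a 3 h signal saturated on 1 of 2 slides, and probe 491 was fitted at 2.35 with a signal saturated on both slides of the 3 h pool, so that its size there is not exact. For probe 490 untreated M. sedula was above background in 3 of 4 channels. Without background correction probe 490 was at 3.32 at 60 min. Probe 1780 was the lowest at 60 min, at -3.58 ± 0.28, and stood at 0.23 ± 0.30 at 3 h. Untreated M. sedula was saturated in 1 of 4 channels for it. Without the 15 min slide probe 509 was at 3.00 at 15 min.

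The slide of 60 min against 15 min of shock in M. sedula asks what differed between these times. In the fit, 92 probes were higher and 61 lower at 60 min, of 2224, and limma's test of hybridisation error called 90. Probe 491 was higher by 2.62 ± 0.30 and probe 490 by 2.55 ± 0.28 on the log2 scale. Probe 963, at -2.78 ± 0.31, and probe 1780, at -2.43 ± 0.28, were the lowest. Without the direct slide 216 were higher and 183 lower. Without the 15 min slide, or the 60 min slide, 90 were higher and 120 lower.

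At 3 h in M. sedula the highest ratio was that of probe 1520, fitted at 5.10 ± 0.37. Its signal was saturated on both slides of the 3 h pool, so its size is not exact, and its channel values give 26.8-fold. Probe 211 was at 3.91 ± 0.32, after 1.50 ± 0.30 at 15 min and 2.62 ± 0.30 at 60 min. Its 60 min and 3 h signals were each saturated on 1 of 2 slides, and for both probes untreated M. sedula was above background in 3 of 4 channels. Probe 861, at -4.86 ± 0.30 (29.0-fold lower), and probe 161, at -4.61 ± 0.32 (24.4-fold lower), were the lowest. At 15 min these were at 0.21 and -0.04. Without background correction the 3 h ratios were 4.66 for probe 1520, 3.51 for probe 211, -4.01 for probe 861 and -3.74 for probe 161. Without the direct slide the 3 h ratios were 3.24 for probe 1520, 4.79 for probe 211 and -3.97 for probe 161, and without any 1 of the other 3 slides of the loop probe 1520 was at 5.72.

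Of the M. sedula probes compared at both times, 43 were at least 2-fold higher and 46 at least 2-fold lower at both 15 and 60 min, where independent lists would share 5.0 and 4.2. At 60 min and 3 h 84 were higher and 98 lower at both times, where independent lists would share 23.0 and 22.0. At all 3 times 27 probes were higher and 28 lower, of 2165. Across probes, which are not independent replicates, the 15 and 60 min ratios correlated at 0.74. Unchanged pools gave 0.50, because these estimates share slides, and the covariance was 0.289 against 0.049 simulated. The 60 min and 3 h ratios correlated at 0.58, with 0 simulated and a covariance of 0.456. Part of these overlaps may come from the shared untreated pool, which could not be split. Without the 15 min slide 229 probes were shared the same way at 15 and 60 min, in place of 89.

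In M. prunae 45 probes were higher and 46 lower after 60 min of shock, of 2256, and 155 were higher and 110 lower after 3 h, of 1967. The 60 min slides had a spot diameter of 90 and the 3 h slides of 200, so time cannot be told apart from slide layout. limma's test of hybridisation error called 81 and 166 probes, the latter likely too many, since its error is likely too small for the 3 h slides. The highest at 60 min were probe 509, at 2.39 ± 0.30, and probe 997, at 1.77 ± 0.26. The lowest were probe 1248, at -2.56 ± 0.25, and probe 1582, at -2.06 ± 0.25. These 60 min directions are likely rather than settled, since they rest on slide names and on the sign of the authors' deposited table. Turned, each 60 min ratio changes sign. At 3 h the highest were probe 1905, at 2.91 ± 0.30, and probe 1141, at 2.70 ± 0.52, and the lowest probe 579, at -1.94 ± 0.32, and probe 247, at -1.87 ± 0.39. The 3 h pool was saturated for probe 1905 and for probe 1141 on 1 of 2 slides. The slides of opposite dye at 60 min correlated at 0.31 across probes after turning. At 3 h median centring in place of loess gave 147 higher and 160 lower. No background correction left 111 probes in place of 265, 81 higher and 30 lower, and the count was 883 without the direct slide. Leaving out either 60 min slide gave 159 or 151 in place of 91. Without the direct 3 h slide probe 1141 was at 5.34, probe 579 at -2.65 and probe 247 at -3.89, and without any 1 of the other 3 slides of the loop probe 1141 was at 1.82 and probe 247 at -1.19. Without background correction probe 1905 was at 2.60, probe 579 at -1.58 and probe 247 at -1.31.

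The M. prunae times shared 18 probes at least 2-fold higher and 6 lower, where independent lists would share 3.4 and 2.5. Their ratios correlated at 0.28 across probes, with 0.01 in simulated unchanged pools. The simulation holds hybridisation error only, and part of the overlap may come from the shared untreated pool, which could not be split. With the 60 min direction turned, 0 would be higher and 2 lower at both times, and the correlation would be -0.28. The shared count, 24 in all, was 15 without background correction, 38 without the first 60 min slide and 39 without the 3 h slide. Probe 1248 was low at both times, at -1.58 ± 0.31 at 3 h, and probe 509 was high at both, at 1.33 ± 0.37.

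Both species were shocked for 60 min and for 3 h, and the labels' comparisons ask how their responses differ. At 60 min 29 probes were at least 2-fold higher and 39 lower in both species, where independent lists would share 4.0 and 3.6. The ratios correlated at 0.61 across probes, with 0 in simulated unchanged pools. These values rest on the likely direction of the M. prunae 60 min slides: turned, 0 probes would be higher and 1 lower in both, and the correlation would be -0.61. At 3 h 56 were higher and 35 lower in both, where independent lists would share 18.8 and 14.8. The 3 h correlation was 0.32, and simulated unchanged pools gave 0.34 because the 4 slides of that loop share errors. The covariance was 0.217 against 0.037 simulated. The simulated error, and with it the simulated covariance, is likely too small for these slides, whose layout differs from that of the 60 min slides. The mean ratio around their loop had an SD of 0.35 across probes. The 3 h shared count, 91 in all, was 40 without background correction and 282 without the M. prunae 3 h slide. Of 1931 probes measured in all 5 shock comparisons, 7 were at least 2-fold higher in all and 4 lower in all, and with the M. prunae 60 min direction turned 0 and 0 would be.

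**Figure D2:**
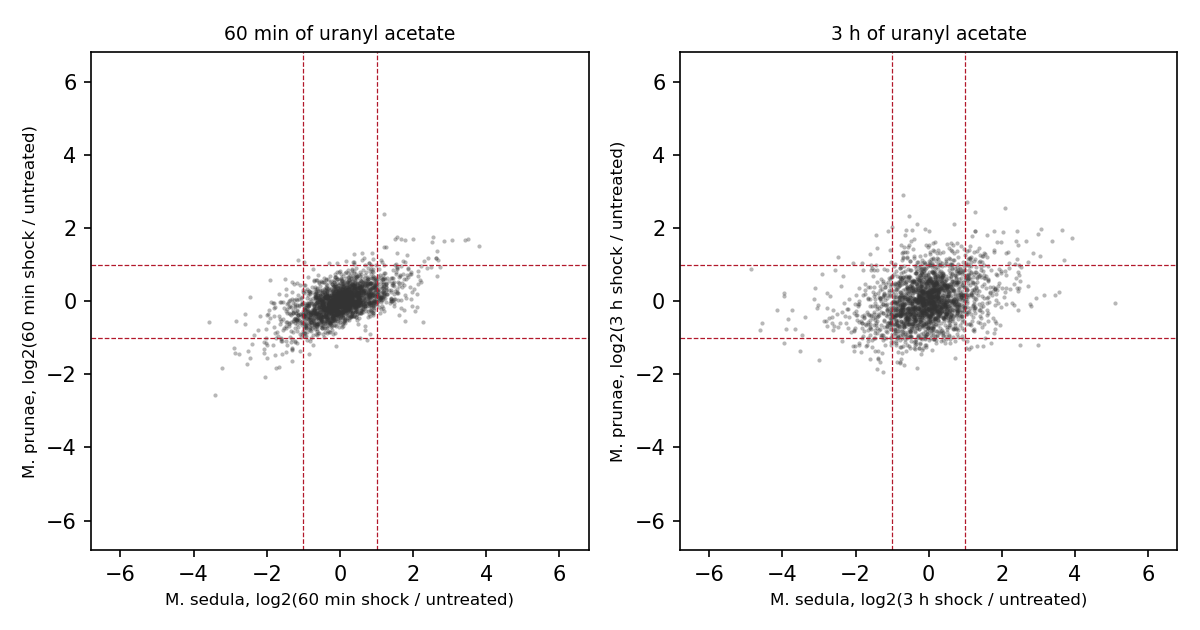
Log2 ratio of shocked to untreated cells in M. sedula (horizontal axis) and M. prunae (vertical axis) after 60 min (left) and 3 h (right) of uranyl acetate; each point is a numbered probe, each ratio joins 2 pools, and dashed lines mark 2-fold. Probes not above background are drawn too. Among those above it, ratios correlated at 0.61 at 60 min (2244 probes), with the M. prunae direction likely rather than settled. At 3 h they correlated at 0.32 (1936 probes), where simulated unchanged pools gave 0.34.

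The response of M. prunae minus that of M. sedula was at least 2-fold for 235 of 2244 probes at 60 min, 108 of them higher and 127 lower in M. prunae. At 3 h it was at least 2-fold for 531 of 1936 probes, 299 higher and 232 lower (302 and 362 with the authors' deposited table). limma's test of hybridisation error in this difference called 18 probes at 60 min and 451 at 3 h. Simulated unchanged pools gave a mean of 37.5 and 19.0 probes at least 2-fold apart. The times lie on slides of different layouts. At 3 h the simulated count is likely too low and the test count too high, since the mean ratio around that loop had an SD of 0.35 across probes. At 60 min the difference was 3.01 ± 0.37 for probe 1780 and 2.58 ± 0.38 for probe 578, which were lower in M. sedula, at -3.58 and -2.47, with M. prunae at -0.56 and 0.12. For probe 1780 the untreated pools were saturated in 2 of 4 channels of M. prunae and 1 of 4 of M. sedula, so its ratios and difference are not exact. For probe 578 each untreated pool was above background in 3 of 4 channels. In the likely direction the lowest differences were those of probe 387, at -2.84 ± 0.39, and probe 1672, at -2.33 ± 0.42. Turned, the differences of probes 1780, 578, 387 and 1672 would be 4.14, 2.35, -1.71 and -1.22, and other probes would lie further out on both sides. At 3 h probe 861 had a difference of 5.75 ± 0.34 and probe 833 of 4.16 ± 0.35. Probe 767 had a difference of -4.19 ± 0.36, with untreated M. sedula above background in 3 of 4 channels and the M. sedula 3 h signal saturated on 1 of 2 slides. Probe 1520 was fitted at -5.15, but its M. sedula 3 h signal was saturated on both slides, so the difference has no exact size. In M. prunae probe 861 stood at 0.89 ± 0.30 at 3 h, and probe 1520 at -0.05 ± 0.37, above background in 1 of 2 channels of the shocked pool. Without background correction the 3 h differences were 5.01 for probe 861, 3.70 for probe 833, -3.63 for probe 767 and -4.45 for probe 1520. The difference of probe 1520 was -3.92 without the M. prunae 3 h slide and -6.39 without the slide of the untreated pair. Without the M. sedula 60 min slide the 60 min count was 437 and probe 1672 was at -1.43. With the M. prunae 60 min direction turned, 336 would be higher and 335 lower at 60 min.

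Untreated M. prunae and M. sedula differed at least 2-fold at 109 of 1966 probes, 64 higher and 45 lower in M. prunae. limma's test of hybridisation error called 54, and simulated unchanged pools gave a mean of 6.4 at least 2-fold apart. Both rest on an error likely too small for this loop. The ratios had an SD of 0.58 across probes, and the mean ratio around the loop 0.35. How many of the 109 stem from hybridisation error thus stays open. On the direct slide M. sedula was dim: median signal over background was 298, background 594, and 42.9% of probes lay above the empty spots. Probe 2186 was lowest in M. prunae, at -6.27 ± 0.32 (76.9-fold), with M. prunae above background in 2 of 4 channels and M. sedula saturated in 1 of 4, so its size is not exact. Probe 485 was fitted at -5.00 ± 0.41. It was saturated in all 4 channels of untreated M. sedula, so its size is not exact: 32.1-fold in the fit and 66.1-fold from channel values. The highest in M. prunae were probe 807, at 3.49 ± 0.43, and probe 1231, at 3.26 ± 0.38. Untreated M. sedula was above background in 3 of 4 channels for probe 807 and in 2 of 4 for probe 1231. Median centring gave 82 higher and 36 lower. No background correction left 67 probes in all, 34 higher and 33 lower, against 189 with the authors' deposited values, 141 higher and 48 lower. The count was 716 without the slide that joins these pools directly, and 67 were higher and 89 lower without any 1 of the other 3 slides of the loop. Without the direct slide the ratios were 5.99 for probe 807, 4.99 for probe 1231, -7.34 for probe 2186 and -7.34 for probe 485, and without any 1 of the others 2.65 for probe 807 and -4.22 for probe 485. Without background correction probe 807 was at 3.00, probe 1231 at 1.80, probe 485 at -4.51 and probe 2186 at -4.64.

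After 3 h of shock the species differed at least 2-fold at 627 of 2243 probes, 343 higher and 284 lower in M. prunae, against 109 in untreated cells. Without the slide of the untreated pair these counts were 750 and 716, but the 716 then sums the error of the other slides of the loop. On the direct slides alone the counts were 797 and 141. Those slides are not alike: in the M. sedula channel 99.2% of probes lay above the empty spots at 3 h and 42.9% in the untreated pair. The offset pulls dim ratios towards 0, which lowers the untreated count. With each direct slide left out the counts were 878 and 716, both with the summed error of the other slides of the loop. How far the counts lie apart thus depends on the slides used. limma's test of hybridisation error called 699, likely too many, since its error is likely too small for this loop. Probe 861 was highest in M. prunae, at 4.95 ± 0.30 (30.8-fold), followed by probe 1231, at 4.62 ± 0.38, for which M. sedula was above background in 1 of 2 channels. Probe 2186 was lowest, at -5.84 ± 0.32, with M. prunae above background in 1 of 2 channels and M. sedula saturated in 1 of 2. Probe 2185 was fitted at -4.64 ± 0.30. M. prunae was not above background in either channel for it, so its size is not exact, and channel values give 17.8-fold lower. The authors' deposited table gave 365 higher and 382 lower. Without the direct slide probe 1231 was at 2.88 and probe 2186 at -4.77, and on that slide alone probe 1231 was at 5.49. Without background correction probe 1231 was at 3.59, probe 2186 at -4.46, probe 861 at 4.42 and probe 2185 at -3.17. The authors' deposited table put probe 2186 at -6.79 and probe 2185 at -5.99.

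On U3O8 the series asks which transcripts, terminal oxidases in particular, differ between the species during growth on the oxide. In M. prunae 130 probes were at least 2-fold higher and 116 lower than in M. sedula, of 2067 compared, and the slides of opposite dye correlated at 0.84 after turning. Probe 1025, at 3.44 ± 0.13 (10.9-fold), and probe 599, at 3.20 ± 0.00 (9.2-fold), were highest in M. prunae. Probe 2186, at -6.13 ± 0.59, and probe 2185, at -4.63 ± 0.66, were lowest, and each was above background in 1 of 2 M. prunae channels. These slides had the dimmest signal, and the authors' deposited table gave 477 probes at least 2-fold apart in place of 246. It put probe 599 at 4.71, probe 2186 at -8.27 and probe 2185 at -8.06, no background correction put probe 2186 at -5.39, and the single slides gave -5.55 and -6.72 for probe 2186 and -3.97 and -5.29 for probe 2185.

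Across 1827 probes measured in all 3 species comparisons, 5 were at least 2-fold higher in M. prunae in each and 14 lower in each. Of these, probe 2186, at -6.27, -5.84 and -6.13 in untreated cells, at 3 h and on U3O8, had the lowest mean, and probe 1025 the highest, at 1.80, 3.51 and 3.44, with its M. prunae 3 h signal saturated on 1 of 2 slides. Across probes the untreated ratios correlated at 0.42 with those at 3 h, where unchanged pools gave 0.34 because these estimates share slides. They correlated at 0.32 with those on U3O8. The ratios at 3 h and on U3O8, which share no slides, correlated at 0.

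**Figure D3:**
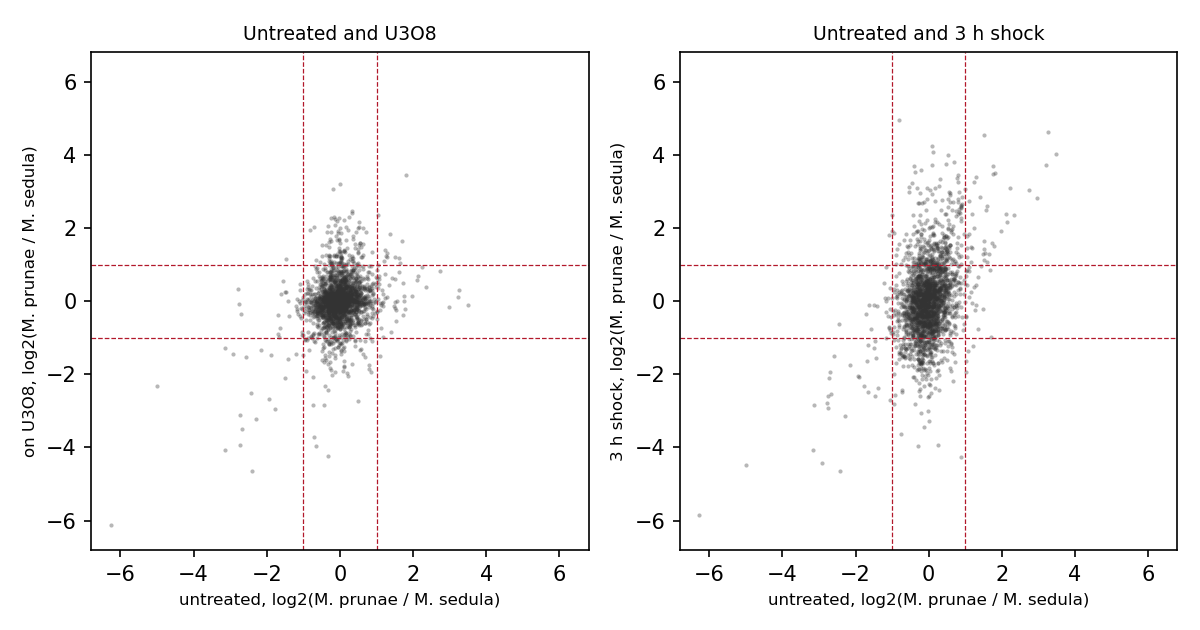
Log2 ratio of M. prunae to M. sedula in untreated cells (horizontal axis) against the ratio on U3O8 (left) and after 3 h of shock (right); each point is a numbered probe, each ratio joins 2 pools, and dashed lines mark 2-fold. Probe 2186 lies at the lower left of both panels, at -6.27 in untreated cells.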

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

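Of the tests in this part, that of the other species comparisons and the turned direction were chosen after the values were seen. After 60 min of shock 1 probe was at least 2-fold apart in opposite directions in the species, and after 3 h 18 were, 8 of them higher in M. prunae and 10 higher in M. sedula. In the likely direction both counts lie below what independent lists of the same sizes would give, which at 60 min is 4.0 and 3.5. The 60 min count is thus no sign of opposed responses. At 3 h the ratios of the species share slides, and simulated unchanged pools correlated at 0.34. This alone lowers the count, so the 18 cannot speak for or against opposed responses. The 60 min count rests on the likely direction of the M. prunae slides: turned, it would be 68. Each stands on 1 pool per condition, and the difference between species was not tested against the spread between cultures. The nc_ probes, which no comparison above uses, gave signal above the empty spots: all 57 did so in both channels of both M. prunae 60 min slides, and 11 in the Cy5 channel of the untreated pair.

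M. sedula had more probes at least 2-fold apart after 60 min than M. prunae, 374 against 91. Noise in the M. sedula estimate would leave few probes in common between separate routes. Yet 290 were at least 2-fold apart the same way both on the direct slide and through the 15 min pool, which argues against noise as the whole cause. Averaging a dye swap in M. prunae alone was also tested: the single M. prunae slides gave 178 and 161 probes, against 402 on the direct M. sedula slide, but they correlated at only 0.31 and shared 52 probes the same way, against the 290 of M. sedula. A difference between species, and between single pools, stays open.

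In untreated cells 16 probes were at least 4-fold lower in M. prunae. Noise of the untreated pair would leave about as many higher as lower on the separate U3O8 slides. There 15 of the 16 were lower, a share of 0.938 (exact 95% binomial interval 0.698 to 0.998, taking probes as independent), which argues against noise as the whole cause. The interval is too narrow, because consecutive numbers correlate (mean 0.253) and the 16 include neighbours such as probes 1123, 1124 and 1125, and 2185, 2186 and 2187. A sequence missing from or diverged in M. prunae may lie behind them: a share of 0.75, 12 of 16, was at least 2-fold lower in both other species comparisons, between the bounds set for and against it. The 3 h ratios share slides with the untreated ratios that picked the probes (0.34 in unchanged pools), so only U3O8 is separate. There probes 1135, 1136 and 395 stood at -0.36, -0.08 and 0.33, and the others were at least 2-fold lower. Ratios of dim spots are pulled towards 0 on those slides. A lower transcript level in M. prunae stays open too, and no genome of either species was used here.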

How the results depend on the processing

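The turned direction, the dye term per layout, the averaged swap and all recomputed overlaps were chosen after seeing the data. Under alternatives other than leaving out a slide, 102 counts stayed within 1.5 times and 6 did not. With the authors' deposited table the count was 477 on U3O8, 189 for untreated species and 170 for M. sedula at 15 min. Without background correction it was 67 for untreated species and 111 for M. prunae at 3 h. The cause was not tested. Dropping the dye term, fitting it per layout and averaging the swap moved no count by more than 1.5 times. In each loop and in the swap every pool carried both dyes equally often. These settings therefore cannot change the ratio of a probe measured on all slides, and they are no check, though they are among the 102. Turning the M. prunae 60 min direction, which turns each of its ratios by construction, gave 671 for the 60 min response difference. Leaving out each slide gave 232 to 285 probes on U3O8, 91 to 159 for M. prunae at 60 min, 242 to 883 at 3 h, 109 to 716 for untreated species, 111 to 435 for M. sedula at 15 min, 374 to 551 at 60 min, 525 to 950 at 3 h, 153 to 4.0e+02 (216 higher and 183 lower) for 60 against 15 min, 627 to 878 between species at 3 h, and 236 to 437 and 531 to 768 for the response differences at 60 min and 3 h. In the loops each highest count came without a slide that joins pools of that comparison directly. Apart from the turned direction, no printed probe changed sign, but of 40 printed ratios from the loops 26 moved by more than their hybridisation SE under at least 1 other alternative and 21 with a slide left out, 31 in all. So did the 4 on U3O8, whose error is only the spread of 2 slides. Of the 6 shared counts 2 moved by more than 1.5 times under at least 1 other alternative (3 with the turned direction), and 4 with a slide left out, such as the M. sedula 15 min and 3 h count, from 59 to 124 without the 15 min slide. The median of the carbon fixation number list in M. prunae at 3 h turned from 0.41 to -0.27 without the M. prunae 3 h slide, in a range up to 0.51. Whether more probes were higher or lower turned under at least 1 alternative in each comparison other than that on U3O8. Median signal over background was lowest on the U3O8 slides. The share of probes above the empty spots was lowest in the untreated M. sedula channel of the untreated pair.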

Other observations

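The test on probe numbers as locus numbers, the turned direction and the lists' subsets below were chosen after seeing the data. The test on shared blocks was added later too, with its bounds written before its own result. The lists were fixed before. Of 48 nc_ probes compared in M. sedula at 3 h, 2 were at least 2-fold higher and 4 lower, and nc_mse0596 was at 2.81 ± 0.32, after 1.06 ± 0.30 at 15 min and 1.33 ± 0.30 at 60 min. Between the species at 3 h 13 of 56 were at least 2-fold apart, with nc_mse0318_ at 3.83 ± 0.34, after 3.18 ± 0.34 in untreated cells.

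Consecutive probe numbers had correlated ratios, with a mean of 0.253 over the 9 comparisons, falling to 0.008 at a distance of 30. A hypothesis is that the numbers are M. sedula locus-tag numbers. The 11 locus-tagged probes correlated with the probe of the same number at a mean of 0.51, higher than at any other offset of -40 to 40, the next being 0.38 at an offset of 1. Single correlations ran from -0.62 to 0.97. The 11 are not all separate loci: 2p_Msed1513, 3p_Msed1513 and 4p_Msed1513 were all set beside probe 1513, at 0.85, -0.62 and 0.65. Probes printed side by side with numbers over 50 apart also correlated, at 0.111 ± 0.011 (SE), within 2 SE of the bound set for nearness, 0.5 times 0.253, but 2139 of 2198 consecutive pairs had no spot in a shared block, and these correlated at 0.25 ± 0.011, which argues against nearness on the slide, or a shared block, as the whole cause.

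If the numbers are locus numbers, which the files do not state, the list set for terminal oxidases and iron oxidation was low in M. sedula after 60 min and 3 h of shock, and not after 15 min. At 15 min 0 of its 45 measured probes were at least 2-fold higher and 2 lower, with a median of 0.11 at percentile 89.3. At 60 min 1 of 45 was higher and 14 lower, and at 3 h 1 of 44 was higher and 15 lower. The medians, -0.46 and -0.56, stood at percentiles 0 and 0.1 of 10000 random lists matched on intensity, and at 0.7 and 0.4 among the same list moved along the numbers, which keeps neighbours together. In M. prunae 4 of 45 were higher and 0 lower at 60 min, and 4 of 42 higher and 1 lower at 3 h. The response difference had a median of 0.64 at 60 min and 0.90 at 3 h, both at percentile 100. With the M. prunae 60 min direction turned, which is likely rather than settled as given, 0 would be higher and 4 lower in M. prunae at 60 min, and the difference would have a median of 0.40 at percentile 99.2 (95.3 moved along the numbers). A block of 7 consecutive numbers had a median of -2.65 in M. sedula at 3 h and of -0.43 in M. prunae. On U3O8 the list split, with 12 higher and 10 lower in M. prunae and a median of 0.13: the same 7 probes had a median of -1.18, with 0 higher and 5 lower, and a further block of 6 a median of 1.96, with 4 higher and 2 lower. A block of 23 had 8 higher and 1 lower, with a median of 0.67. Both readings rest on the mean of 0.51 above.

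On the same assumption, 2 of 3 probes of the copper resistance list were at least 2-fold higher in M. sedula at 60 min, with a median of 3.49, and 2 of 3 in M. prunae, with a median of 1.50, whose sign changes if the 60 min direction is turned. The sulfur list had a median of -0.35 in M. sedula at 3 h, at percentile 4.0 (13.8 moved along the numbers), and of 0.70 between species at 3 h, at percentile 99.9 (96.9). On U3O8 its median between species was -0.39, at percentile 0.8 (3.0). The carbon fixation list had 5 of 17 higher and 1 lower in M. sedula at 60 min, with a median of 0.24 at percentile 86.3, and none of 17 at least 2-fold apart on U3O8. Its medians were 0.26 in M. sedula at 15 min, at percentile 97.3 (97.4 moved along the numbers), and 0.41 in M. prunae at 3 h, at 98.2 (97.2), the last turning to -0.27 without the M. prunae 3 h slide. Between untreated species its median was -0.24, at percentile 3.3, and the 60 min response difference had -0.34, at 3.0 (2.6), or -0.21, at 25.6, with the 60 min direction turned. These lists describe single pools and carry no test.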
